A study of Homo sapiens with 4 samples.

How the data were processed

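Stranded libraries of poly(A) RNA were sequenced from 4 samples, which the labels give as 2 control and 2 MDM2-overexpressing cultures of U251, an established human glioblastoma line, grown with 1 ug/ml puromycin and 10% fetal bovine serum. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The series holds a table of counts per gene and library and a table of the authors' comparison.

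The deposited count table holds whole-number counts per gene, not normalized, in 4 columns headed Vector or MDM2 with a replicate number. Vector was taken as the control of the labels. Per the submitters' processing notes, STAR, DESeq and the human build GRCh38 were used, with no version or role given. The gene counter, its strand setting and the annotation are not given in the sources used here, and the gene names in both tables are those of Drosophila. In the deposited table of the comparison, the authors' baseMean is a signal, their mean normalized count over all 4 libraries. The authors' log2 fold change is on the log2 scale as MDM2 over Vector. The standard error and test statistic in the deposited table are a score each. The p-value and adjusted p-value in the deposited table are the authors' own. The ratio of baseMean recomputed from the 4 count columns to the deposited one was 1 for each of the 11463 genes with a count, so both tables come from the same counts. The name of the comparison's file carries a term that no label explains. Of the gene names, 5 in each file had become a month and a number.

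Rows that name no gene stayed out of library sizes and tests. In the 4 libraries, reads outside any feature were 2.91% to 3.38% of all rows' counts, ambiguous reads 7.47% to 8.00%, and reads aligned at several places 6.03% to 6.84%. Counts on named genes were 42985746 to 45172099 per library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A gene at 0 in both libraries of a group was set to a floor of 3 counts over the group, and for genes with 1 to 20 Vector counts the ratio of summed counts is given with an exact 95% binomial interval. Because the strand setting of the counting is not stated, reads of overlapping and antisense genes may not be told apart. Close copies in gene families can share reads. Human coordinates do not apply to these names, and a fly genome was not used here, so no positions are given.

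Genes were filtered with filterByExpr, scaled with TMM factors and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment over 9609 genes, at a threshold of 0.05. The standard error is the absolute log2 fold change divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes, and values of a list in one library over the Vector mean add 0.1 CPM before the log2, which understates changes of low genes. Gene lists with at least 4 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 28 lists, and again with an estimated correlation. The fry test asks another question, whether a list shifted in one direction against no change rather than against the other genes. Its mixed form counts changes in either direction. None of the 10 list calls held with an estimated correlation. The camera direction and the list median differed in sign for the lists of apoptosis and DNA damage, cadherin, UDP-glycosyltransferase, odorant binding and insulin genes. The mean and the median differed in sign for the lists of glia, testis, apoptosis and DNA damage, RAS-RAF-ERK, and P450 and transferase genes. Both the edgeR and the camera steps were tested on data simulated for the comparison of MDM2 with Vector over 9609 genes. Of 50 genes raised 2-fold, 40 were recovered, and of 50 raised 4-fold, 49. Of 50 lowered to 0.5 of their level, 40 were recovered, and of 50 lowered to 0.25, 49. Of 9340 unchanged genes, 22 were called. Beside the 40, 49, 40 and 49 true calls, these 22 were a larger share of all calls than the threshold of 0.05 in this single simulation. In a second simulated set of the same genes, a list raised 2-fold was called and 0 of 28 other lists were. Each gene was simulated independently and with the same dispersion in both groups, whereas the spread of the real pairs differed. The simulations therefore cannot show how often lists of correlated genes would be called falsely.

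The design, the alternatives, 32 lists with 660 human genes and the naming rule were fixed before the data were examined. Only 3 of those names occur in the tables (SPARC, PCNA and CCT2), so the human lists could not be tested. SPARC had a log2 fold change of −0.35, PCNA of 0.14 and CCT2 of 0.23, and none of them passed in edgeR. In their place, 30 lists of Drosophila genes were written after the gene names, the mean levels over all libraries, the first 3 rows of the authors' table and 1 annotated row of it had been seen, and before any difference between groups was computed. The rule named the 10 largest increases and the 10 largest decreases among genes past the threshold with a mean of at least 50 counts and no overlap between the groups. From each list it took up to 4 members past the threshold, or the 2 most abundant where none passed. Names made of CG and a number are annotation numbers and were kept. The alternatives were DESeq2 size factors, library totals alone, DESeq2 1.42.0, limma-voom, no filter, a mean of at least 50 counts, the replicate number as a block, each library left out, and stricter thresholds. With a library left out, its lone partner was assumed to vary like the other group. The filter was also run again, so the measured members of a list could differ. Robust dispersions and the fly lists were added after the data had been seen.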

Results

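Messenger RNA was sequenced from 4 samples that the labels describe as the human glioma line U251, 2 controls and 2 that overexpress MDM2, an E3 ubiquitin ligase. The deposited tables do not hold human genes. Of their 13926 named rows, 6909 carry a CG number, the annotation style of Drosophila, 148 (1.06%) match a human gene symbol, and 0 are named MDM2 or contain GFP. The most abundant gene was ninaE, the major fly rhodopsin, with 3.89% of the counts on average, followed by mt:CoI with 2.21% and mt:CoIII with 1.37%. Arr1, a photoreceptor arrestin, took 0.572% and the photoreceptor channel gene trp 0.322%. The level of MDM2, which would have checked the labels, therefore has no value in these tables, and neither has any of MDM4, BRAF, CDH1, CDH2, VIM or SNAI1. All values below compare the libraries headed Vector, matched to the control labels, with the libraries headed MDM2, and none of them measures MDM2 overexpression in U251 cells.

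Each library held a similar number of counts on named genes, with 45065268 in Vector 1, 44946476 in Vector 2, 45172099 in MDM2 1 and 42985746 in MDM2 2. Across genes, log2 CPM (counts scaled to library size) correlated at r = 0.9928 between the Vector libraries and at 0.9775 between the MDM2-headed libraries, against 0.9552 to 0.9646 between groups. Genes are not independent replicates, so these values only describe the libraries. The biological coefficient of variation was 0.105 between the Vector libraries and 0.267 between the MDM2-headed ones, and in both pairs the counts differed by more than sampling noise.

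The comparison of the groups was meant, by the labels, to show which transcripts change with MDM2 overexpression. In the libraries headed MDM2, a set of genes nearly absent from the Vector libraries was clearly detected, and cuticle, immune and fat body genes were among those that were lower. CG3397 had 0 counts in both Vector libraries and 760 and 691 in MDM2 1 and MDM2 2, at least 503-fold higher against a floor of 3 counts over the Vector group. The digestive serine protease gene Jon65Aiii rose from 4 counts in each Vector library to 3283 and 1546, a ratio of summed counts of 627 (95% interval 318 to 1450). Of the genes that fell, phu changed most, from 477 ± 85.5 CPM to 68.1 ± 21.9 CPM (SD, n = 2 each), or 7.01-fold lower. In edgeR's quasi-likelihood test, 180 of 9609 genes passed a Benjamini-Hochberg adjusted p of 0.05, 62 higher and 118 lower in the MDM2-headed libraries. Without adjustment, 1954 of the 9609 had a p under 0.05 in that test. Counts of list members below are to be read against these rates. With either Vector library left out, 2 genes passed, CG3397 and CG4962 (outside the naming rule and named after its value was seen). Leaving out MDM2 1 gave 412 genes, 182 higher and 230 lower, and leaving out MDM2 2 gave 554, of which most were higher (356 against 198).

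Of the 10 largest increases, each started from at most 12 counts over the Vector libraries together. Phae1, a serine protease gene, went from 0 counts to 173 and 163, at least 116-fold higher. Alp2, an alkaline phosphatase gene, had 3 and 2 counts in the Vector libraries and 7743 and 1261 in MDM2 1 and MDM2 2, a ratio of 1870 (95% interval 802 to 5770). Mur29B, a mucin-related gene, was the closest in its replicates among those with a Vector count, at 480 and 395 counts against 2 and 1, a ratio of 303 (103 to 1470). The organic anion transporter gene Oatp33Eb had 231 and 125 counts against 0 and 1, a ratio of 370 (66 to 14700). CG13905 had 1226 and 378 counts in MDM2 1 and MDM2 2, a ratio to the Vector libraries of 1670 (299 to 65900). CG14292 had 4094 and 1047 counts there, a ratio of 534 (290 to 1120). For CG18480 they were 199 and 87, a ratio of 297 (52.9 to 11800), and CG13323 had a ratio of 246 (141 to 477). Unlike the others, CG13323 was higher in MDM2 2, with 2158 counts against 686 in MDM2 1. These intervals cover counting error only. The adjusted p of edgeR's test for the 10 genes ran from 0.00448 for CG3397 to 0.0427 for Alp2.

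The 10 largest decreases were smaller in fold and started from higher counts. After phu (log2 fold change −2.81 ± 0.27 SE), thw fell with a log2 fold change of −2.67 and the sodium channel subunit gene ppk3 with −2.40. CG5653 was at −2.30, ImpL1 at −2.29 and CG6026 at −2.02. CG15096 was the most abundant of the remainder and went from 207 ± 28.9 CPM to 51.9 ± 8.29 CPM (SD, n = 2 each). Cpr76Bc, a cuticle protein gene, was 4.07-fold lower, CG13280 3.63-fold and CG12256 3.56-fold. The edgeR adjusted p of the 10 lay between 0.00772, for thw and CG12256, and 0.0457 for ImpL1.

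**Figure D1:**
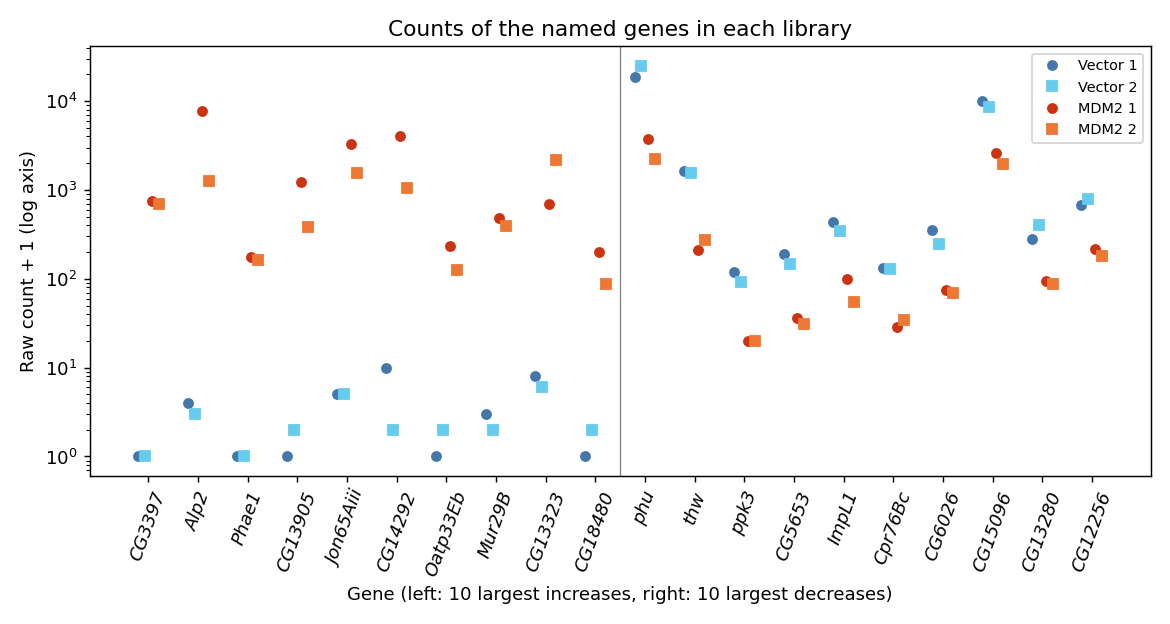
Raw counts plus 1 (log axis) of the 10 genes with the largest increases and the 10 with the largest decreases, one point per library. The left genes had at most 12 counts over both Vector libraries, and Alp2 differed between the MDM2-headed libraries, with 7743 and 1261 counts.

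Genes of trypsins, Jonah proteases and other gut enzymes had higher estimates in the MDM2-headed libraries, mainly through MDM2 1. Of 46 genes on the list, 18 passed the filter, and 14 of these had a higher estimate, with a median log2 fold change of 4.10. Members nearly absent from the Vector libraries could pass the filter only with counts in the MDM2-headed libraries, which favors a positive median. In edgeR over all genes tested, Jon65Aiii rose and the amylase gene Amy-d fell, from 497 ± 64.3 CPM to 250 ± 10.0 CPM (SD, n = 2 each), and 16 did not pass. Adjusted over the list alone, 8 rose and 1 fell. DESeq2 called 8 of the 18, limma-voom 1, and 13 had an unadjusted p under 0.05 in edgeR. The median of the members over the Vector mean was 4.83 on the log2 scale in MDM2 1 and 0.92 in MDM2 2. Some members were at their Vector level in MDM2 2, such as Jon74E (45 and 39 counts in the Vector libraries, 1923 in MDM2 1 and 42 in MDM2 2, chosen after its values were seen). The list's share of the counts, to which the amylases add much, was 0.115% and 0.103% in the Vector libraries, 0.177% in MDM2 1 and 0.0817% in MDM2 2. The list was higher in limma's camera test with the preset correlation (adjusted p = 0.00595), and the adjusted p was 0.916 with an estimated correlation. Without MDM2 1 the median was 1.04, and without Vector 1, Vector 2 or MDM2 2 it was 7.20, 6.57 and 7.46. The filter was rerun each time, so these medians were not held to the same 18 members. The Jonah, trypsin and amylase genes have close copies, and reads could be split between them.

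Heat shock genes had higher estimates in the MDM2-headed libraries in all 22 measured members, with a median log2 fold change of 0.96. Hsc70-2, a member of the Hsp70 family, rose from 2.80 ± 0.0862 CPM to 17.2 ± 0.795 CPM (SD, n = 2 each), with a log2 fold change of 2.62 ± 0.10 SE and an edgeR adjusted p of 0.00448. It was the only member to pass over all genes in edgeR, and 8 rose adjusted over the list alone. DESeq2 called 10 of the 22, limma-voom 1, and 12 had an unadjusted p under 0.05 in edgeR. The Vector libraries differed from each other here, with list medians of −0.31 in Vector 1 and 0.26 in Vector 2 around their mean, against 0.80 and 0.99 in MDM2 1 and MDM2 2. The list was higher in camera (adjusted p = 2.13e-07), with an adjusted p of 0.868 with an estimated correlation. Its median was 0.55 without Vector 1 and 1.36 without Vector 2. The Hsp70 copies on this list are nearly identical in sequence, so their separate counts are uncertain.

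Antimicrobial peptide and immune induced genes had lower estimates in the MDM2-headed libraries in 27 of 28 measured members, with a median log2 fold change of −0.94. DptA, the antibacterial peptide diptericin, fell from 273 ± 80.5 CPM to 86.4 ± 2.77 CPM (SD, n = 2 each), 3.15-fold lower (edgeR adjusted p = 0.0409). PGRP-SA, a peptidoglycan recognition gene of the Toll pathway, fell from 25.1 ± 0.26 CPM to 13.4 ± 0.904 CPM. The remaining 26 did not pass over all genes in edgeR, and 12 fell adjusted over the list alone. DESeq2 called 12 of the 28, limma-voom 2, and 15 had an unadjusted p under 0.05 in edgeR. The list median over the Vector mean was −0.60 in MDM2 1 and −1.34 in MDM2 2. In camera the adjusted p was 7.14e-08, and it was 0.826 with an estimated correlation. Without MDM2 2 the median was −0.57 and without MDM2 1 it was −1.39.

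Fat body and hemolymph genes had lower estimates in 14 of 18 measured members, with a median log2 fold change of −0.34. Lsp1beta, a larval serum protein gene, fell with a log2 fold change of −1.40 and Obp99b with −0.88, and 16 did not pass in edgeR. Adjusted over the list alone, 7 fell. DESeq2 called 7 of the 18, limma-voom 1, and 8 had an unadjusted p under 0.05 in edgeR. The camera adjusted p was 0.00134, against an adjusted p of 0.721 with an estimated correlation. Of 8 measured yolk protein and eggshell genes, 0 passed in edgeR over all genes and 4 fell adjusted over the list alone, with a median of −1.19. At an unadjusted p under 0.05 there were 6, with DESeq2 2 and with limma-voom 0. Yp3 had a log2 fold change of −0.29 ± 0.11 SE and Yp1 of −1.23 ± 0.25 SE. This list had a camera adjusted p of 0.00578 and of 0.721 with an estimated correlation, and its call ended without MDM2 2 (median −0.80, adjusted p = 0.0735). The Yp genes are related in sequence.

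Cuticle protein genes included 4 that fell in edgeR and 33 that did not pass, of 37 measured. DESeq2 called 9 of the 37, limma-voom 3, and 14 had an unadjusted p under 0.05 in edgeR. Cpr72Ec, a component of the corneal lens, went from 1470 ± 106 CPM to 515 ± 35.2 CPM (SD, n = 2 each), 2.85-fold lower. Cpr47Ee fell with a log2 fold change of −1.68 and Cpr100A with −1.76, besides Cpr76Bc above. The median log2 fold change was −0.36. Adjusted over the list alone, 9 fell and 1 rose. The camera adjusted p was 0.000628, and 0.721 was the adjusted p with an estimated correlation. The list of eye structure and pigment genes shares Cpr72Ec, and its second member to fall was ry, the xanthine dehydrogenase of eye pigment synthesis, at 2.46-fold lower. Its other 17 measured members did not pass in edgeR, and 7 of the list fell when adjusted over it alone. DESeq2 called 6 of the list, limma-voom 2, and 8 had an unadjusted p under 0.05 in edgeR. The median was −0.14 (camera adjusted p = 0.00982, and adjusted p = 0.721 with an estimated correlation).

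**Figure D2:**
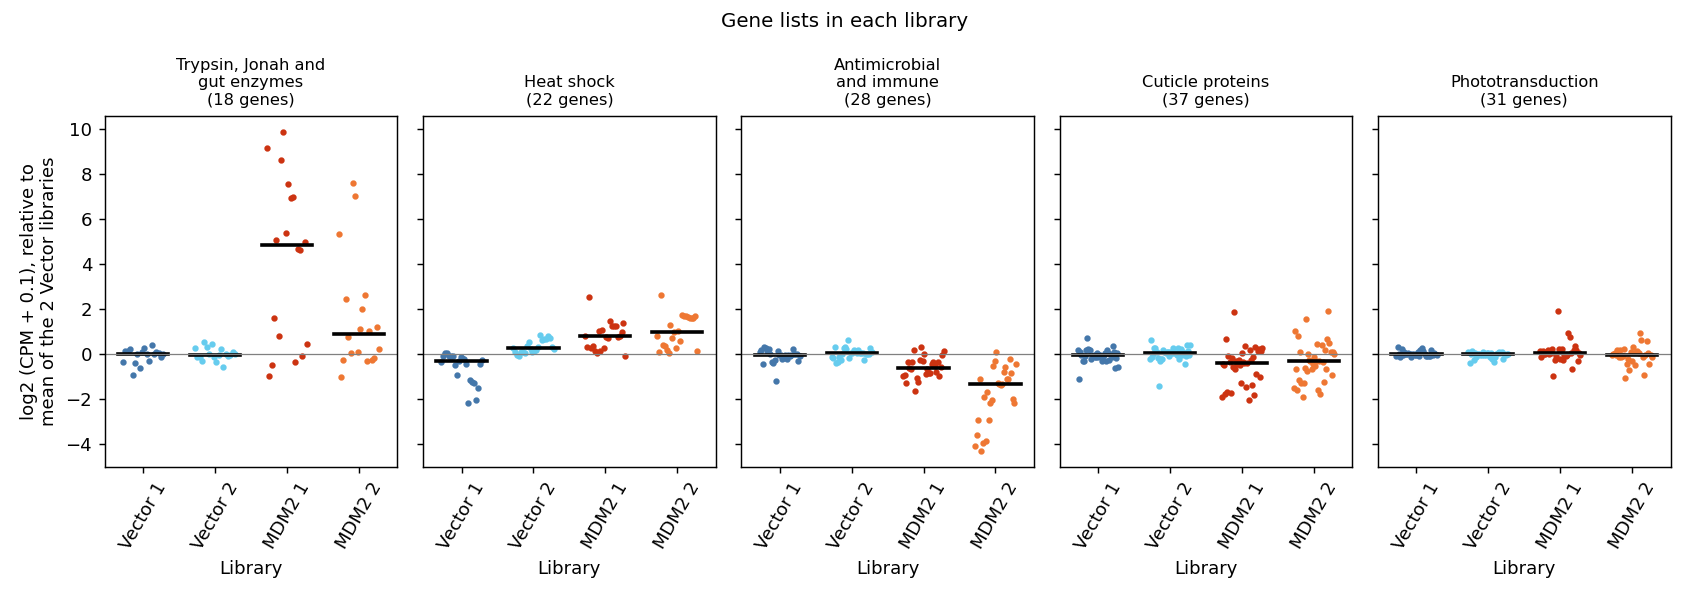
Log2 (CPM + 0.1) of the measured genes of 5 lists relative to the mean of the 2 Vector libraries, one point per gene and library, with the list median as a black bar. The gut enzyme list has medians of 4.83 in MDM2 1 and 0.92 in MDM2 2, and the immune list of −0.60 and −1.34.

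Phototransduction genes took 7.15% to 8.02% of the counts in each library and showed no shift as a group, with a median log2 fold change of 0.02 over 31 measured members (camera adjusted p = 0.932). Rh2, the rhodopsin of the ocelli, rose from 93.1 ± 0.282 CPM to 178 ± 1.76 CPM (SD, n = 2 each), 1.92-fold higher with an edgeR adjusted p of 0.00809. The photoreceptor lipid phosphatase gene laza fell from 105 ± 2.30 CPM to 52.0 ± 2.17 CPM, 2.01-fold lower with an adjusted p of 0.00983. The other 29 did not pass in edgeR, and 2 rose and 3 fell adjusted over the list alone. DESeq2 called 6 of the 31, limma-voom 2, and 10 had an unadjusted p under 0.05 in edgeR. The list's median changed sign when library totals replaced the scaling factors.

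The fly counterparts of the pathways named in the title of the study held few calls, but calls were few over all genes too. In edgeR 180 of 9609 genes passed, and 1954 had an unadjusted p under 0.05. These lists were therefore not shown to change less than other genes. Of 23 RAS-RAF-ERK pathway genes, 0 passed in edgeR over all genes or in limma-voom, 1 passed in DESeq2 and 3 had an unadjusted p under 0.05. The median log2 fold change was 0.01 (camera adjusted p = 0.932). In that list csw had a log2 fold change of 0.01 ± 0.14 SE and spen of 0.07 ± 0.21. The 2 genes of 14-3-3 proteins, too few for camera and with 0 calls in edgeR, DESeq2 or limma-voom, had log2 fold changes of 0.07 ± 0.13 SE for 14-3-3zeta and 0.05 ± 0.14 for 14-3-3epsilon, within their errors. The list of cadherin, Snail family and matrix protease genes also holds laminin, collagen, integrin and other genes, such as LanA, vkg and mys. Of its 23 measured members, 0 passed in edgeR or limma-voom, 1 in DESeq2 and 3 at an unadjusted p under 0.05. The median was 0.02 (camera adjusted p = 0.932), with arm, the fly beta-catenin, at 0.03 ± 0.08 SE and scrt at 0.11 ± 0.26. The RAS-RAF-ERK and cadherin medians changed sign with library totals. Ku80, a DNA end-joining gene, was the 1 member of 19 apoptosis and DNA damage genes that passed in edgeR. It fell by 0.55 on the log2 scale (edgeR adjusted p = 0.0481). Of the 19, 1 passed in DESeq2, 0 in limma-voom and 6 had an unadjusted p under 0.05. That list's median was −0.01 (camera adjusted p = 0.932).

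Ribosomal protein, neuron and muscle genes had small positive medians whose calls depended on single libraries. Of 83 cytosolic ribosomal protein genes, 80 had higher estimates and 0 passed in edgeR, DESeq2, limma-voom or at an unadjusted p under 0.05, with a median log2 fold change of 0.10, RpL3 at 0.19 ± 0.14 SE and RpL5 at 0.12 ± 0.13. Their camera adjusted p of 0.00529 became an adjusted p of 0.936 with an estimated correlation, 0.962 without Vector 1 and 0.942 without MDM2 1. Neuron and synapse genes (21 measured, 0 passed in edgeR over all genes or in limma-voom, 2 rose adjusted over the list alone, 4 in DESeq2 and 3 at an unadjusted p under 0.05) had a median of 0.14 and a camera adjusted p of 0.0329, with 0.929 as the adjusted p with an estimated correlation. Their median turned to −0.05 without Vector 2 and the call ended without MDM2 2 (adjusted p = 0.458). Atpalpha was at 0.14 ± 0.22 SE and cpx at 0.15 ± 0.28. Muscle genes (20 measured, 0 passed in edgeR or limma-voom, 6 in DESeq2 and 4 at an unadjusted p under 0.05) had a median of 0.13 and a camera adjusted p of 0.041, with an adjusted p of 0.721 with an estimated correlation. This call ended with any library left out, at adjusted p values of 0.0695 to 0.213, and Argk was at 0.20 ± 0.12 SE and Act57B at −0.22 ± 0.11.

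Of 47 cytochrome P450 and glutathione transferase genes, GstE7 rose 1.92-fold and GstD3, Cyp6a8 and Cyp4e3 fell 1.84-fold, 1.66-fold and 1.65-fold (camera adjusted p = 0.711). Adjusted over the list alone, 8 of the 47 rose and 11 fell, 24 had an unadjusted p under 0.05, and 18 passed in DESeq2 and 2 in limma-voom. Ugt86Dd fell 1.87-fold among 14 UDP-glycosyltransferase genes (0.905), the 1 to fall adjusted over the list alone. Of the 14, 2 passed in DESeq2, 0 in limma-voom and 3 had an unadjusted p under 0.05. Of 32 odorant binding protein genes, Obp19c, Obp83ef, Obp99b and Obp56h fell, by 1.99-fold, 1.86-fold, 1.84-fold and 1.47-fold (0.905). Adjusted over that list alone, 2 rose and 6 fell, 13 had an unadjusted p under 0.05, and 6 passed in DESeq2 and 2 in limma-voom. The P450, transferase and odorant binding genes include close copies.

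The other 11 lists tested did not pass in camera and held 0 members past the edgeR threshold over all genes. Of their 223 measured members, 42 had an unadjusted p under 0.05 (1954 of all 9609 genes did), 21 passed in DESeq2 and 0 in limma-voom. Adjusted over each list alone, 1 glia, 2 Turandot, 3 clock and 1 insulin gene fell, 1 clock and 1 dosage compensation gene rose, and the other 6 lists had 0. Glia genes had a median log2 fold change of −0.01 over 12 members (adjusted p = 0.932), with Gs2 at −0.18 and nrv2 at −0.03. Testis and sperm genes had a median of 0.04 over 15 (0.636), with bol at −0.01 and mia at −0.23. That median turned to −0.28 without MDM2 1 or MDM2 2, and without Vector 1 the list passed as lower (−0.27, adjusted p = 0.00807). Turandot and JAK-STAT stress genes had −0.08 over 15 (0.0714), and the list passed without Vector 2 (median −0.41, adjusted p = 0.000415). There vir-1 was at −0.34 and TotA at −0.04. ER stress genes had 0.04 over 18 (0.621), with Hsc70-3, also on the heat shock list, at 0.34 and GstD1, also on the transferase list, at 0.13. Circadian clock genes went both ways around a median near 0 over 15 (0.621), with Pdp1 at −0.04 and sgg at 0.03, and 4 of them passed in DESeq2. The clock members farthest from 0, chosen after their values were seen, were tim at −0.97, cwo at −0.71, to at −0.56 and Pdf at 0.52. Chemosensory receptor genes had 0.20 over 72 (0.129), with Ir75a at −0.38 and Ir75b at −0.63, and passed with library totals (adjusted p = 0.0444) and without Vector 1 (0.0187). Cell cycle and DNA replication genes had −0.11 over 27 (0.216), with E2f1 at −0.03 and Top2 at 0.01. Insulin and nutrient genes had 0.01 over 19 (0.599), a sign that library totals turned, with Desat1 at −0.39 and FASN1 at 0.34. Mitochondrially encoded genes had 0.06 over 13 (0.231), with mt:CoI at 0.19 and mt:CoIII at 0.29. Histone genes had −0.07 over 6 (0.599), with His3.3B at 0.05 and His4r at 0.04. Dosage compensation and sex determination genes had 0.03 over 12 (0.636), with Sxl at 0.06 and fru at 0.12. On the accessory gland list 3 genes were measured, too few for camera. Of these 0 passed in edgeR, DESeq2, limma-voom or at an unadjusted p under 0.05. There EbpIII, named for the ejaculatory bulb, was at −0.20 and antr at −0.27.

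The authors' deposited table of their own comparison had the same direction, MDM2 over Vector. In the authors' deposited table, 911 genes had an adjusted p under 0.05, 422 higher and 489 lower. All 180 edgeR calls were among them, each with the same sign. Fold changes in the authors' deposited table correlated with those of edgeR at r = 0.9997 across 9605 genes. DESeq2 run on the same counts called 913 genes, 911 of them shared with the authors' deposited table.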

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

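Robust dispersions and the use of fly lists were chosen after the data had been seen. The count of changed genes depended on the settings. Against 180 (62 higher, 118 lower), library totals gave 257 (79 higher, 178 lower), DESeq2 gave 913 (423 and 490), limma-voom 118 (34 higher), no filter 82 (34 and 48), a mean of at least 50 counts 104 (39 and 65) and robust dispersions 359 (119 and 240). Of the 180 genes, 117 were shared with limma-voom, 82 with no filter, 104 with the mean of at least 50 counts and 173 with robust dispersions. Among the 41 named genes that passed, 19 no longer passed with limma-voom and 21 with no filter. The mean of at least 50 counts ended 17 of these calls and robust dispersions 4, and no gene reversed. The stricter threshold of 0.01 gave 26 (15 and 11), and a fold of at least 2 gave 89 (48 and 41), so the lower majority turned under both. The authors' deposited table had 604 calls at 0.01 against 911. DESeq2 size factors gave 194. With 1 library left out, the counts ran from 2 to 554, with 2 to 356 higher and 0 to 230 lower. Without MDM2 2 the lower majority also turned, to 35.7% lower, and without either Vector library both genes were higher. The low end came with either Vector library left out, when the spread was estimated from the MDM2-headed pair alone. Of the 41 named genes that passed, 40 no longer passed without Vector 1 and 40 without Vector 2, with none reversed. The MDM2 transcript level, which has no row in the tables, could not be computed under any setting.

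The replicate numbers are shared by the groups. The deviations of Vector 1 and MDM2 1 from their group means correlated at −0.0784 across genes, and with only 2 pairs the numbers were not shown to pair the samples. With the replicate number as a block, 297 genes passed (155 higher and 142 lower, or 47.8% lower against 65.6% without it, so the majority turned here too), 154 of them shared with the 180. Under the block the neuron list (median 0.17, adjusted p = 0.0544) and the muscle list (0.13, adjusted p = 0.0872) no longer passed in camera. Of values that did not pass, bol moved to 0.06, TotA to 0.13, and Pdp1 and the medians of the clock and insulin lists to 0.00.

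None of the 10 list calls held with an estimated correlation, which left the medians as they were. Except for neuron (0.197) and ribosomal protein genes (0.599), the 10 had unadjusted p values of 0.00076 to 0.018 in fry's mixed test. Low values there also came from lists without a camera call, such as phototransduction (0.000324) and P450 and transferase genes (0.000827). In fry's directional test, which tests a list against no change and not against the other genes, none of the 10 passed. The fry adjusted p values were 0.0746 for the eye structure list (median −0.14), 0.554 for neuron (0.14), 0.0825 for muscle (0.13), 0.0825 for fat body (−0.34), 0.277 for yolk (−1.19), 0.277 for immune (−0.94), 0.22 for heat shock (0.96), 0.277 for gut enzymes (4.10), 0.171 for cuticle (−0.36) and 0.719 for ribosomal protein genes (0.10). With library totals the muscle list no longer passed (0.10, adjusted p = 0.0545) and the chemosensory receptor list passed (0.18, adjusted p = 0.0444). Library totals also turned csw to −0.01, Top2 to −0.01, and the phototransduction, RAS-RAF-ERK, cadherin and insulin medians to 0.00, −0.02, −0.01 and −0.01. With no filter the yolk list no longer passed (−0.63, adjusted p = 0.094), and the testis and UDP-glycosyltransferase medians turned to −0.13 and −0.01. With a mean of at least 50 counts the odorant binding, insulin and histone medians turned to −0.04, −0.08 and 0.04. With limma-voom, bol was at 0.06 and TotA at 0.13.

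Leaving out 1 library at a time changed some list calls. The ranges of the medians were −0.05 to 0.40 for neuron, 0.07 to 0.11 for muscle, −1.39 to −0.80 for yolk, 0.00 to 0.20 for ribosomal protein, −0.28 to 0.17 for testis, −0.41 to 0.01 for Turandot and 0.00 to 0.26 for chemosensory receptor genes. Without Vector 1 the testis list was lower with an adjusted p of 0.00807. Medians near 0 crossed it in other lists that did not pass, with ranges of −0.06 to 0.03 for glia, −0.14 to 0.00 for insulin, −0.12 to 0.00 for histone, 0.00 to 0.05 for apoptosis, −0.14 to 0.10 for RAS-RAF-ERK, −0.10 to 0.12 for cadherin, −0.12 to 0.14 for UDP-glycosyltransferase, −0.03 to 0.05 for phototransduction, −0.18 to 0.02 for clock, and −0.08 to 0.01 for P450 and transferase genes. So did named genes that did not pass, namely Atpalpha (−0.12 to 0.44), cpx (−0.19 to 0.59), nrv2 (−0.08 to 0.02), bol (−0.41 to 0.54), antr (−0.74 to 0.09), TotA (−0.59 to 0.85), csw (−0.13 to 0.18), spen (−0.18 to 0.36), 14-3-3zeta (−0.05 to 0.19), 14-3-3epsilon (−0.11 to 0.22), scrt (−0.21 to 0.51), Pdp1 (−0.36 to 0.36), sgg (−0.18 to 0.26), E2f1 (−0.16 to 0.11), Top2 (−0.02 to 0.05), His4r (−0.04 to 0.12) and Sxl (−0.28 to 0.51). Because the filter was rerun each time, the members behind a list median could change as well. The cause of these changes was not tested.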

Other observations

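Of the tests below, the one on the median of a second midgut list over both MDM2-headed libraries was chosen before its result was seen, and all the others after. Genes outside the naming rule, picked after their values were seen, also passed the edgeR threshold. The transporter gene blot rose from 74492 and 78267 counts in the Vector libraries to 250419 and 227155 in the libraries headed MDM2, a log2 fold change of 1.70 (adjusted p = 0.0162). Rgl rose with a log2 fold change of 1.33, and gig, the fly TSC2, rose from 2536 and 2798 counts to 5859 and 5945 (edgeR adjusted p = 0.00772 for both). The nuclear receptor gene Hr38 was at 1.05 (adjusted p = 0.0256), and the neuropeptide genes Dsk and Dh31 were at 0.89 and 0.45 (0.0420 for both). The GATA factor gene GATAe was low in all libraries and rose from 2 and 1 counts to 98 and 72 (adjusted p = 0.0162). Among decreases, Jhe (juvenile hormone esterase) changed by −1.36, ImpL3 (lactate dehydrogenase) by −1.14, retinin of the corneal lens by −0.95 and Hn, phenylalanine hydroxylase, by −0.70, with edgeR adjusted p values of 0.0177, 0.0217, 0.0361 and 0.0492. The mucin gene Muc68D did not separate the groups (edgeR adjusted p = 0.225) and had 41996 counts in MDM2 2 and 18 in MDM2 1, against 65 and 3 in the Vector libraries.

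The gene names belong to another organism than the labels give. Reads of human U251 cells would put almost none of the counts on phototransduction genes, but the lowest share in any library was 7.15%, which argues against them. Fly tissue without photoreceptors is argued against as well, since that share was at least 34.4 times the share of testis, gut enzyme and yolk genes together, which took at most 0.233%, and ninaE was the most abundant gene with 3.89% on average. Which tissue with photoreceptors it was stays open. Of the 34 phototransduction genes 31 passed the filter, but that list was written after the gene names and mean levels had been seen, so eye or head tissue cannot be told apart from other material that holds photoreceptors by it. Whether a table of another study was deposited under these labels was not tested, and no biological explanation was tested.

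Gut enzyme genes had higher estimates in the MDM2-headed libraries, mainly through MDM2 1. Movement of reads between paralogs would leave the family sum in place, but the summed CPM of 28 Jonah and trypsin genes was at least 14 times the Vector mean in both libraries (109.8 times in MDM2 1). A single uniform gut source is argued against by the SD of 1.79 for the log2 ratio of MDM2 1 to MDM2 2 over 20 genes. These had been picked as raised in MDM2 1, and the Vector level was not subtracted. Part of this spread may come from those choices. Carry-over of gut tissue into MDM2 1 stays possible but was not shown. Of 17 genes on the second midgut list, 8 passed the filter, with a median log2 fold change of 3.64. Their median over the Vector mean was 2.93 in MDM2 1. Members nearly absent from the Vector libraries could pass the filter only with counts in the MDM2-headed libraries, so a positive median was partly built in. The list had 0 of the 8 past the threshold in edgeR or limma-voom, 3 in DESeq2 and 5 at an unadjusted p under 0.05. Its members moved unequally: yip7 had 5, 4, 8174 and 1152 counts in Vector 1, Vector 2, MDM2 1 and MDM2 2, LManVI 14, 2, 4369 and 6, and lab 186, 178, 218 and 143. Peritrophin-A was at a log2 fold change of 0.00, and Muc68D, also on this list, was high in MDM2 2 alone. For MDM2 2 carry-over cannot be told apart from other sources, because the list's median there was 0.06 in a single library, with members from −0.25 to 10.16, and a difference between the groups themselves also stays open, as untested.

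Immune genes had lower estimates in the MDM2-headed libraries in 27 of 28 members, of which 2 passed over all genes in edgeR. DESeq2 called 12 of the 28. The list did not pass in camera with an estimated correlation (adjusted p = 0.826) or in fry's directional test (0.277). A lower share of fat body, which makes many of these peptides, may account for all or part of this and cannot be told apart here, because the libraries are too few. The immune median lay below the fat body median by a difference of −0.60. With libraries as replicates the group difference was −0.65 (95% t interval −1.96 to 0.66). This interval was computed after other comparisons had been tried and dropped. A bootstrap over genes, which are not independent, had put the difference below 0, and the spread of single fat body genes had been larger than it. The low level of MDM2 2 alone is argued against by the median of −0.57 without that library. A difference in immune state between the groups stays open, as untested, and so does any difference in how the material was kept.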
